A study of Homo sapiens with 4 samples.

How the data were processed

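Gene expression was measured in U937, a human cell line established from a lymphoma and with features of monocytes, on Affymetrix U133A GeneChip arrays. Per the labels, 1 culture was left untreated and 3 cultures were exposed to paeoniflorin at 0.16 mg/ml for 30 min and then kept at 37°C for 0, 3 or 6 h. The labels do not state when the untreated culture was harvested, so a ratio over it can include a difference of time in culture. Paeoniflorin is a glycoside found in peony root. Total RNA was treated with DNase, and biotin-labelled cRNA was made from it with the manufacturer's one-cycle kit, per the labels' protocols. Each condition is 1 array, 4 arrays in all, and the number of arrays limits the precision of every value.

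The authors deposited 1 signal intensity per probe set and array on a linear scale, for 22283 probe sets. The algorithm that made these intensities, its background correction and any detection call are not given in the sources used here. The mean of each array after trimming 2% of the values on each side lay between 500.20 and 500.21, so the arrays already shared a scale and the deposited intensities were used without further scaling. No column was left without a sample. The array medians were 118 for untreated cells, 115 at 0 h, 122 at 3 h and 111 at 6 h.

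Control probe sets of the manufacturer, 68 in number, were kept out of counts, floors and lists, which left 22215. Gene names came from the platform annotation at GEO. Of the 22215 probe sets, 19065 carried exactly 1 gene symbol, 1043 carried several and 2107 were unnamed there. The Entrez numbers of 19059 probe sets were found in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. That table was used for names alone, and no coordinates are given. A gene was represented by its brightest probe set, that is, the one with the highest mean log2 signal over the 4 arrays among those with that single symbol. This gave 11963 genes. A probe set with several symbols was assigned to no gene.

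Each value under its own array's 50th percentile was raised to that floor before log2 was taken. A gene entered a comparison when at least 1 of its 2 arrays was at or above the floor. Where the dimmer array was under the floor the fold is a lower bound, written as "at least", and a log2 ratio bounded from above as "or lower". Each time after paeoniflorin was compared with the untreated array, and genes were counted by a rule of size, 2-fold or more. With 1 array per condition there is no estimate of the spread between cultures, so no test was made and no p-value is given. As a yardstick, a robust SD of the log2 ratio between the untreated and 0 h arrays was computed in 20 bins of brightness. It takes in the noise of 2 arrays together with any effect of the 30 min exposure.

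Gene lists, 23 in number, were fixed before the data were examined. They cover heat shock proteins and HSF1 targets, the unfolded protein response with ATF4 targets, NRF2 and oxidative stress, metallothioneins, immediate-early genes, NF-kB and inflammatory genes, interferon response, p53 targets, pro-apoptotic and anti-apoptotic genes, G1/S and G2/M cell cycle genes, histones, cholesterol synthesis and uptake, glycolysis and hypoxia, proteasome subunits, cytosolic ribosomal proteins, mitochondrial oxidative phosphorylation, monocyte and macrophage differentiation, immature myeloid granule genes, RNA splicing and nuclear stress, and 2 lists of markers of other cell types. A list member was measured when its mean log2 signal reached the mean floor, as 6612 genes did. The median log2 ratio of a list was set beside 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart when its median fell in the outer 5% of those lists. That describes these arrays and is not a test of the treatment.

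The genes named in the text were chosen by a rule, also fixed before the data were examined. It took, for each time, up to 12 genes with the highest and up to 12 with the lowest log2 ratio among those past the size rule with both arrays above the floor, up to 3 lower bounds in each direction, every measured heat shock gene, and up to 4 members of each other list by the size of their ratio. Probe sets shared by HSPA1A and HSPA1B or by HSPA8 and small RNA genes, and the genes IER3, BTG1, GCLM, GCLC, MYLIP and UBL3, fall outside that rule and were chosen after their values were seen.

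The 3 comparisons share the untreated array, so their correlations and overlaps were set beside values simulated with no change on any array, from 100 draws, and beside comparisons with no array in common. Noise in every simulation was set from the untreated and 0 h arrays, the pair with the smallest spread. The counting step was tested on simulated data for 3 h against untreated, over 6998 genes. It called 1 of 66 genes changed 1.5-fold, 58 of 67 changed 2.5-fold, 61 of 67 changed 4-fold, and 13 of 6801 unchanged genes. In a simulated 6 h comparison over 6599 genes, a list of 25 genes raised by 0.30 on the log2 scale gave a median of 0.24 and stood apart. Of 200 smaller random lists in the simulated 0 h comparison, where nothing was changed, 7 stood apart. Genes were simulated independently, so this does not cover lists whose members vary together.

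Alternatives were quantile normalization, centring on the median, floors at the 40th and 60th percentile, no floor with the 10th percentile added to each value, leaving out probe sets whose names end in _x_at or _s_at, the median over all probe sets of a gene, the 0 h array as baseline, and size rules of 1.5-fold and 3-fold. The median over all probe sets also took in those under the floor on both arrays, which can shrink the ratio of a gene. A heat shock list with the shared probe sets added was chosen after seeing the data. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.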

Results

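U937 cells were profiled without treatment and at 0, 3 and 6 h after a 30 min exposure to paeoniflorin at 0.16 mg/ml, a compound that the study describes as an inducer of heat shock proteins. The question was which genes respond to it. Each of the 4 conditions was 1 array with no replicate, so the differences below carry no replicate check and no test. Signals were the deposited intensities, with array maxima of 49668 for untreated cells, 47719 at 0 h, 63520 at 3 h and 48649 at 6 h. The signal ratio of 3' to 5' probe sets was 1.18, 1.14, 1.15 and 1.09 for ACTB and 0.953, 0.956, 0.846 and 0.959 for GAPDH, in the order untreated, 0 h, 3 h and 6 h. Hybridisation spikes, 18 probe sets, had median log2 ratios over untreated of −0.02 at 0 h, 0.17 at 3 h and −0.14 at 6 h (SD 0.11, 0.11 and 0.12). Of the lymphoid marker genes, 12 of 15 lay below the floor, with a median signal of 46.1 in untreated cells and 34.5 at 6 h. Erythroid, epithelial and stromal markers were below it for 13 of 16 genes, with medians of 24.6 and 24.2.

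The heat shock genes were the first group of interest. Probe sets shared by HSPA1A and HSPA1B, the genes of the stress-inducible cytosolic chaperone HSP70, were 2-fold or more higher at 6 h. Their signals went from 976 in untreated cells to 2825 at 6 h (2.89-fold) for 200799_at, from 818 to 1967 (2.40-fold) for 200800_s_at, which also lists HSPA1L, and from 512 to 1042 (2.03-fold) for 202581_at. At 3 h the same probe sets had log2 ratios of −0.37, −0.07 and −0.13, and at 0 h of −0.02, 0.01 and −0.34. Because each carries several symbols, the signal cannot be divided between HSPA1A and HSPA1B.

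For the 19 other measured heat shock genes, no ratio or bound of the brightest probe set reached 1.5-fold at any time. The members with the highest log2 ratios at 6 h were HSPA4L, an HSP110 family chaperone, at 0.58, the co-chaperone BAG3 at 0.43, and the HSP40 genes DNAJA1 at 0.35 and DNAJB1 at 0.33. The HSP90 genes HSP90AA1 and HSP90AB1 were at 0.10 and 0.00, HSPH1 at 0.07, the small heat shock protein gene HSPB1 at −0.08, and the mitochondrial chaperonins HSPD1 and HSPE1 at 0.00 and 0.16. HSPA6, a stress-inducible HSP70 gene, was at −0.35 at 0 h and −0.17 at 6 h and at least 1.42-fold lower at 3 h, a bound that leaves the size open. The transcription factor gene HSF1 had 0.18, −0.48 and −0.04 at the 3 times. The remaining members, HSPA4, DNAJB5, DNAJB6, CHORDC1, STIP1, FKBP4 and CACYBP, lay between −0.26 and 0.05 at 6 h. Other probe sets went the opposite way at 6 h for STIP1 (0.32), HSPA6 (at least 0.11), HSPH1 (−0.04), HSP90AA1 (−0.08), HSPA4 (−0.03) and CACYBP (0.05), and at 0 h for HSF1 (−0.46 or lower). The list's median log2 ratio was −0.01, 0.00 and 0.00, inside the range of matched random lists each time. Probe sets shared by HSPA8, the constitutive HSP70 gene, and small RNA genes were at 0.17, 0.37 and −0.02 at 6 h.

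**Figure D1:**
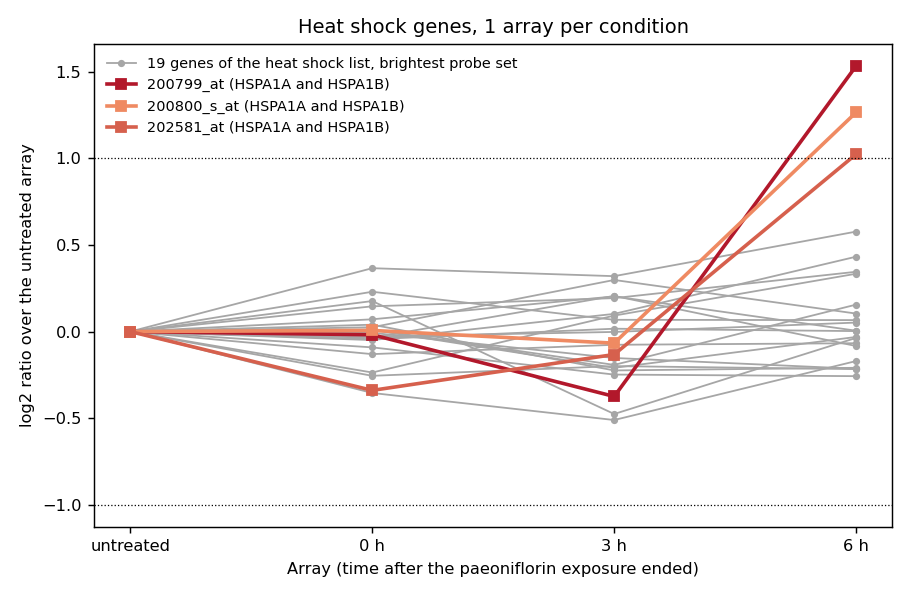
Log2 ratio over the untreated array at 0, 3 and 6 h after paeoniflorin, for 3 probe sets shared by HSPA1A and HSPA1B (coloured squares) and for 19 measured heat shock genes (grey circles), with 1 array per point and dotted lines at 2-fold. The shared probe sets reach 1.53, 1.27 and 1.02 at 6 h, while the highest of the other genes, HSPA4L, is at 0.58.

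Directly after the exposure, at 0 h, few genes differed from untreated cells. FAM114A2 was 2.60-fold higher (134 to 347), S100A13, a small calcium-binding protein gene, 2.59-fold higher (165 to 427), and ICAM2, an adhesion molecule gene, 2.08-fold higher (479 to 995). ANKRD11, a chromatin regulator gene, was 2.93-fold lower (340 to 116) and the kinase gene PSKH1 2.12-fold lower (412 to 195). In all, 12 of 6957 genes were at least 2-fold higher and 5 were lower, 5 of these 17 as bounds; of 11619 probe sets, 19 were higher and 11 lower. The other genes higher included DLEU2, ATP2C1, FARP1, SCML1 and APOBR, at 2.06-fold to 2.13-fold, with bounds of at least 2.89-fold for the tetraspanin gene CD82, 2.56-fold for CACNG4 and 2.27-fold for ARHGAP33. FKBP8 and ARMC7 were 2.10-fold and 2.07-fold lower and TPBG at least 2.12-fold lower.

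Of the 7 other probe sets of these genes, 2 had the same direction and 0 of them reached 1.5-fold. S100A13, FARP1 and ATP2C1 had other probe sets going the opposite way, at −0.24 or lower, −0.37 and, for ATP2C1, −0.18 and −0.05. None of the 16 named genes past 2-fold at 0 h stayed past it under all alternatives. DLEU2 was lost only with the median over probe sets, although no other probe set of this gene reached the floor on either array. The robust SD of log2 ratios between the untreated and 0 h arrays, for genes of similar brightness, ran from 0.17 for ICAM2 to 0.37 for FKBP8.

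At 0 h, 2 gene lists stood apart. The metallothionein genes had a median log2 ratio of −0.11, with 1 of 6 above 0, and 0.88% of matched random lists lay lower. All 6 were read by probe sets ending in _x_at, so this list could not be scored without such probe sets. The anti-apoptotic genes had a median of 0.23, with 6 of 8 above 0, and 0.22% of random lists lay higher. Its members BIRC2, BCL2L1 and BCL2A1 were at 0.42, 0.39 and 0.24, and by the brightest probe sets no member of either list was 1.5-fold from untreated. A second MT1F probe set went the opposite way from its list, at 0.75 (772 to 1301). With the median over the probe sets of each gene, neither list stood apart (−0.08 and 0.10).

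At 3 h more genes differed from untreated cells. TIPARP, a mono-ADP-ribosyltransferase gene, was 4.81-fold higher (684 to 3290), EGR3, a zinc finger transcription factor gene, 4.71-fold higher (158 to 742), KLF10 4.09-fold higher (303 to 1240) and MAFF, a small MAF factor gene, 3.48-fold higher (234 to 816). CCL2, a chemokine that attracts monocytes, was 3.46-fold higher (676 to 2338) and SLC30A1, a zinc exporter gene, 2.80-fold higher (871 to 2436). CYP1A1, a cytochrome P450 of xenobiotic metabolism, was at least 3.30-fold higher (83.2 to 391). CPOX, an enzyme of heme synthesis, was 3.21-fold lower (877 to 273).

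Among 7007 genes, 39 were at least 2-fold higher at 3 h, 10 of them as bounds, and 26 were lower, 5 as bounds. Of 11736 probe sets, 67 were higher and 55 lower. In the simulation without change in those genes, 13 of 6801 were past the rule. Its noise came from the untreated and 0 h arrays, whose log2 ratios had a robust SD of 0.17, against 0.29 for 3 h over untreated. The simulation may therefore understate how many unchanged genes pass at 3 h. Other genes higher included SLC22A4 (2.99-fold), the AP-1 subunit gene FOSL1 (2.84-fold), ICAM2 (2.57-fold), GPR183, an oxysterol receptor gene (2.56-fold), FCAR, the IgA receptor gene (2.52-fold), and CDK17 (2.39-fold), with ZNF175 at least 2.86-fold and CACNG4 at least 2.78-fold higher. Lower genes included ERBIN (2.54-fold), MAPKBP1 (log2 ratio −1.32), CALML4 (2.40-fold), the methionine salvage gene APIP (2.32-fold), FOS (2.27-fold, 641 to 282), ZEB2 (2.21-fold), the splicing kinase gene CLK2 (2.20-fold), PSKH1 (2.19-fold), UGDH (2.15-fold), CSGALNACT2 (2.10-fold) and TIMM10B (2.09-fold). PARG, ARMC7 and PSMC3IP were at least 2.79-fold, 2.44-fold and 2.38-fold lower.

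Of 16 other probe sets of the 2-fold genes at 3 h, 10 had the same direction, and 3 of them reached 1.5-fold. The second probe set of MAFF was at least at 1.57 and those of FCAR at 0.50 and 1.47, whereas the other probe sets of ICAM2 and CALML4 went the opposite way, at −0.03 and 0.12. Under all alternatives that measured them, 10 of the 31 named genes stayed past 2-fold: TIPARP, EGR3, KLF10, MAFF, CCL2, SLC30A1, CPOX, APIP, CLK2 and UGDH.

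Of the gene lists, 2 stood apart at 3 h. Immediate-early genes, which respond to signals within minutes, had a median of 0.17, and 4 of 25, EGR3, KLF10, FOSL1 and IER3, were at least 2-fold higher while 1, FOS, was lower. At 1.5-fold 5 were higher and 4 lower. Of the matched random lists, 1.92% lay higher. This list no longer stood apart under 5 of 8 alternatives, over which its median ran from 0.08 to 0.20. Cytosolic ribosomal protein genes had a median of 0.25, with 21 of 25 above 0 and none 1.5-fold from untreated, and 0.025% of random lists lay higher. RPL24, RPS19, RPS6 and RPS16 were at 0.51, 0.50, 0.44 and 0.43. The 3 h array also read higher for bright genes in general, with a median of 0.12 in the brightest of 20 bins, and with quantile normalization the ribosomal median was 0.06 and no longer apart.

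At 6 h the genes higher than in untreated cells included enzymes against oxidative stress, and several immediate-early genes were lower. HMOX1, the gene of heme oxygenase 1, was at least 3.44-fold higher (85.9 to 406), NQO1, a quinone reductase gene, 2.75-fold higher (581 to 1599), and SQSTM1, the gene of the autophagy receptor p62, 2.24-fold higher (896 to 2004). CCL2 was 4.73-fold higher (676 to 3198), TNFRSF12A, the TWEAK receptor gene, 3.49-fold higher (186 to 652) and FCAR 3.39-fold higher (290 to 982). EGR1, a zinc finger transcription factor gene, was 7.96-fold lower (1174 to 148) and FOS 5.18-fold lower (641 to 124). DUSP1, a phosphatase of MAP kinases, was at least 2.94-fold lower (327 to 73.8) and ZFP36, which promotes mRNA decay, 2.44-fold lower (490 to 201).

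At least 2-fold higher at 6 h were 30 of 6982 genes and lower were 40, with 5 bounds in each direction. With quantile normalization the split was 32 higher and 27 lower. Of 11677 probe sets, 51 were higher and 89 lower. Other genes higher included GPR183 (2.90-fold), SLC30A1 (2.75-fold), the activation marker CD69 (2.49-fold), SP2 (2.47-fold), MED17 (2.40-fold), CDC42EP3 (2.29-fold) and SLC25A40 (2.25-fold), with THBD, the thrombomodulin gene, at least 3.43-fold and CYP1A1 at least 2.90-fold higher. Other genes lower included PSKH1 (2.90-fold), the phosphodiesterase gene PDE4B (2.67-fold), PNRC1 (2.53-fold), FUT8 (2.51-fold), CBY1 (2.48-fold), the receptor phosphatase gene PTPRO (2.39-fold, 2458 to 1026), GOLGA2 and WDR37 (both 2.35-fold) and ST3GAL2 (2.32-fold). SLC24A1 and NAV2 were at least 2.27-fold and 2.25-fold lower.

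Of 31 other probe sets of the 2-fold genes at 6 h, 26 had the same direction and 12 of them reached 1.5-fold. EGR1's second probe set was at −1.68 or lower, those of FCAR at 1.27 and 1.82, and those of CDC42EP3 at 1.06 and 1.25. NQO1's other probe sets were at 1.07 and 0.10, those of GOLGA2 at −0.10 and −0.46, and that of THBD at 0.49. Under all alternatives that measured them, 14 of the 31 named genes stayed past 2-fold: CCL2, TNFRSF12A, FCAR, GPR183, NQO1, SLC30A1, CD69, MED17, CDC42EP3, EGR1, FOS, PNRC1, ZFP36 and WDR37. HMOX1, CYP1A1 and DUSP1 fell under 2-fold with a floor at the 60th percentile. With the median over the probe sets of a gene, DUSP1, SQSTM1 (0.54) and GOLGA2 (−0.46) fell under 2-fold. DUSP1 and SQSTM1 had no other probe set at or above the floor on either array. Their loss therefore came from probe sets under the floor and shows no disagreement between measured probe sets. THBD did so under 3 alternatives.

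**Figure D2:**
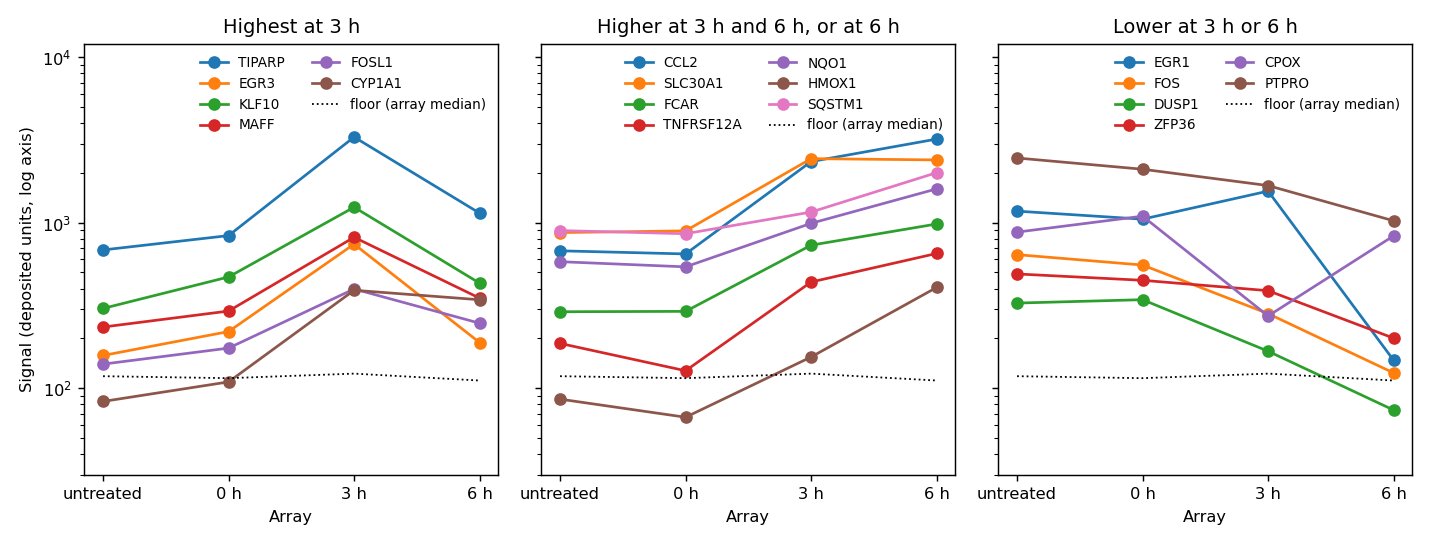
Signal on a log axis on each of the 4 arrays, 1 array per point, for named genes highest at 3 h (left), higher at 3 h and 6 h or at 6 h (middle) and lower at 3 h or 6 h (right), with the floor of each array dotted. TIPARP reads 684, 835, 3290 and 1142 in order, CCL2 reads 676, 647, 2338 and 3198, and EGR1 reads 1174, 1050, 1551 and 148.

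In the list of NRF2 and oxidative stress genes, 3 of 19 were at least 2-fold higher at 6 h, 6 were at least 1.5-fold higher and 0 were 1.5-fold lower. Besides HMOX1, NQO1 and SQSTM1 these were TXNRD1, the thioredoxin reductase gene, at 0.83, and the glutathione synthesis genes GCLM and GCLC at 0.70 and 0.63. The list's median was 0.19, with 0.125% of matched random lists higher, and it stood apart under all 8 alternatives (0.14 to 0.23). At 3 h the median was 0.09, inside the random range, with NQO1 at 0.77 and HMOX1 at least 1.31-fold higher, and one other NQO1 probe set at −0.76. At 0 h it was −0.05.

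Immediate-early genes had a median of −0.27 at 6 h, and 0.14% of matched random lists lay lower. At least 2-fold lower were 5 of 25, EGR1, FOS, DUSP1, ZFP36 and BTG1, and 10 were at least 1.5-fold lower against 1 higher, FOSL1 at 0.82. EGR3 and KLF10, among the highest genes at 3 h, were at 0.26 and 0.51. The list no longer stood apart with a floor at the 60th percentile, and without probe sets ending in _x_at or _s_at its median was 0.03.

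Another 5 lists stood apart at 6 h. Unfolded protein response and ATF4 genes had a median of −0.13, with HERPUD1 at −0.95 and VLDLR at −0.74, although SLC7A11, the cystine transporter gene, was 2.17-fold higher. Immature myeloid granule genes had a median of −0.11, with MYB at −0.71 and PRTN3 at −0.52. Anti-apoptotic genes had a median of 0.24, with 5 of 8 above 0, BCL2A1 at 0.90 and MCL1 at 0.48. Cholesterol synthesis genes had a median of 0.15, with 12 of 16 above 0 and HMGCS1 at 0.51. In that list MVD and SREBF1 went the other way, at −0.50 and −0.48. Proteasome subunits had a median of 0.11, with 22 of 26 above 0 and PSMA5 at 0.49. Of these 5 lists, cholesterol synthesis stood apart under 7 of 8 alternatives and the unfolded protein response under 6. Granule genes did so under 5 and the remaining lists under 4. The direction turned for the unfolded protein response without probe sets ending in _x_at or _s_at (0.01) and for anti-apoptotic genes over 0 h (−0.07). Of 69 list comparisons, 11 stood apart, and by time these were 2, 2 and 7 of 23. Lists of independent genes would give 3.45, but members of a list may vary together and all comparisons share the untreated array.

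**Figure D3:**
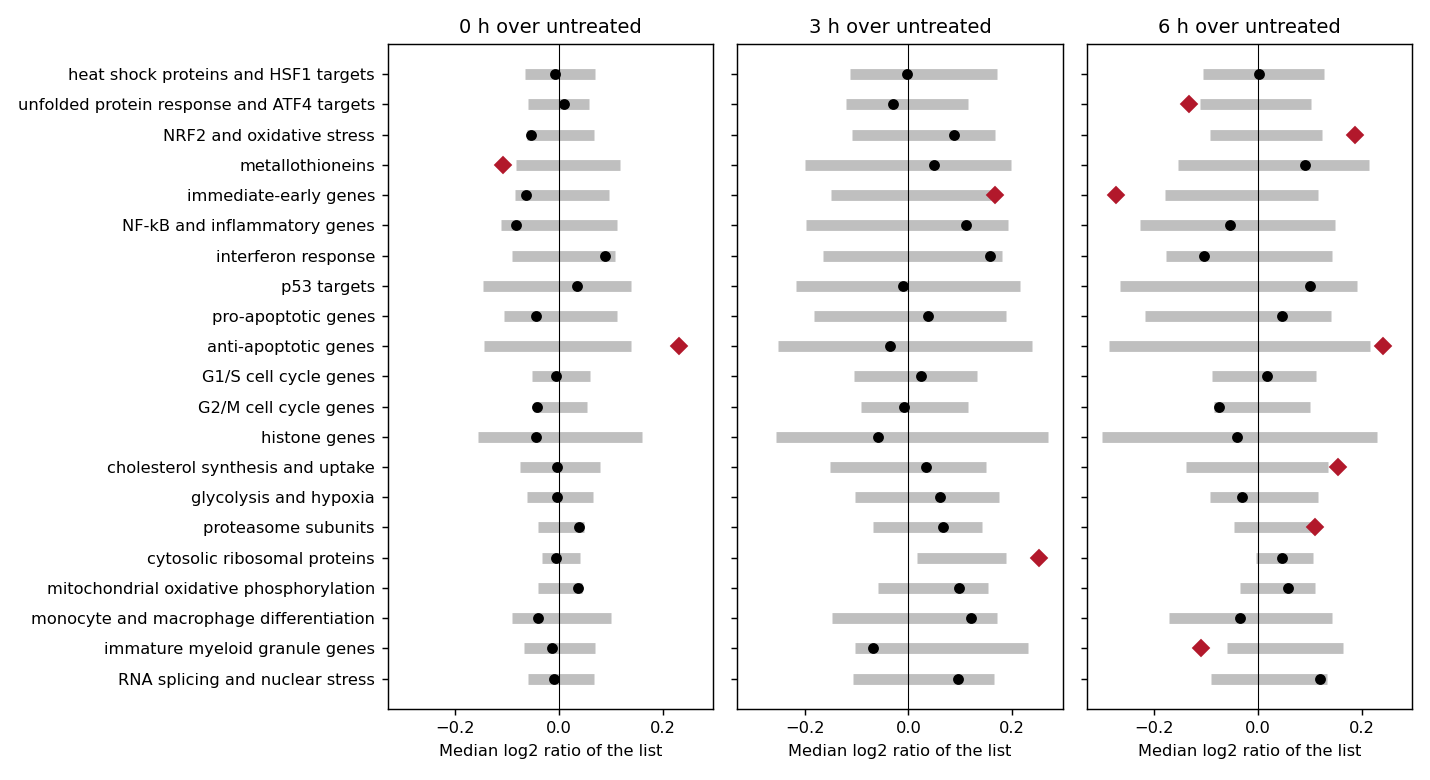
Median log2 ratio over untreated of 21 gene lists at 0, 3 and 6 h (1 array per time), as red diamonds for lists in the outer 5% of 10000 matched random lists and black circles for the others, with grey bars for the central part of the random lists. The immediate-early list moves from 0.17 at 3 h to −0.27 at 6 h, and the NRF2 list is at 0.19 at 6 h.

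The remaining lists lay inside the random range at every time over untreated cells. NF-kB and inflammatory genes had medians of −0.08, 0.11 and −0.05 at 0, 3 and 6 h, and CCL2 was the 1 member of 14 past 2-fold, while CXCL8 and IL1B were at −0.90 and −0.73 at 6 h. Over the 0 h array the 3 h median of this list was 0.35 and stood apart, as did those of monocyte and macrophage genes at 0.22 and metallothioneins at 0.20. Interferon response genes had 0.09, 0.16 and −0.10, with IRF1 at 1.07 at 3 h and 0.91 at 6 h. Genes of p53 targets had 0.03, −0.01 and 0.10 and pro-apoptotic genes −0.04, 0.04 and 0.05, with no member past 2-fold. G1/S genes had −0.01, 0.02 and 0.02, G2/M genes −0.04, −0.01 and −0.07, and histone genes −0.04, −0.06 and −0.04. Glycolysis and hypoxia genes had 0.00, 0.06 and −0.03, mitochondrial oxidative phosphorylation genes 0.04, 0.10 and 0.06, and splicing genes −0.01, 0.10 and 0.12, where the kinase gene CLK1 was at 0.95 at 6 h. Monocyte and macrophage genes had −0.04, 0.12 and −0.03, with CEBPA, a myeloid transcription factor gene, at 0.67 and 0.83 at 3 and 6 h and the integrin gene ITGAM at −0.43 at 3 h, where its other probe set was at least at 0.39, and at least 1.70-fold lower at 6 h.

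Lists that stood apart at another time had these medians elsewhere. Metallothioneins were at 0.05 at 3 h and 0.09 at 6 h (the second MT1F probe set at 1.01 and 1.33), anti-apoptotic genes at −0.03 at 3 h, immediate-early genes at −0.06 at 0 h, and ribosomal protein genes at 0.00 at 0 h and 0.05 at 6 h. Unfolded protein response genes were at 0.01 and −0.03, cholesterol synthesis genes at 0.00 and 0.03, proteasome subunits at 0.04 and 0.07, and granule genes at −0.01 and −0.07, each at 0 and 3 h. Of the marker lists of other cell types, the 3 measured lymphoid genes had medians of −0.07, 0.38 and 0.04, and the 3 measured erythroid, epithelial and stromal genes −0.07, 0.16 and 0.08. Medians and means differed in sign for 15 of the 69 list comparisons, and 0 of these 15 stood apart.

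Over time, 25 genes were 2-fold higher at 3 h alone, among them TIPARP, EGR3, KLF10, MAFF and FOSL1, and 20 at 6 h alone, among them NQO1, HMOX1 and SQSTM1. Higher at both 3 and 6 h were 8 genes, including CCL2, CYP1A1, FCAR, GPR183, SLC30A1 and TNFRSF12A. Lower at 3 h alone were 20 genes, at 6 h alone 35, and at both 3 and 6 h 4, FOS, MYLIP, NAV2 and UBL3. At all 3 times, CACNG4 was higher and PSKH1 lower, but these ratios share the untreated array, and over the 0 h array CACNG4 was at 0.12 at 3 h and PSKH1 at −0.05 and −0.45 at 3 and 6 h. CCL2, CYP1A1, FCAR, SLC30A1 and TNFRSF12A were 2-fold higher on both late arrays than on both early arrays (untreated and 0 h), and NAV2 and UBL3 lower; the other 2 ways of pairing the arrays gave 0 genes. With centring on the median, a floor at the 60th percentile or without probe sets ending in _x_at or _s_at, 0 genes were lower on both late arrays.

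The 3 h and 6 h changes were then compared across genes, which are not independent replicates. The log2 ratios of 6612 genes at 3 h and 6 h over untreated correlated at 0.45. The shared untreated array alone gave 0.50 in simulation, but the covariance was 0.051 against 0.023 simulated. For comparisons with no array in common, 3 h over untreated with 6 h over 0 h, the correlation was 0.22 against a simulated 0.00, and it was 0.16 for 3 h over 0 h with 6 h over untreated. At 0 h the covariance exceeded the simulated one by 0.0040 with 3 h and by 0.0097 with 6 h, and 0 h over untreated correlated at 0.069 with 6 h over 3 h. Of the genes entered at both times, 9 were 2-fold higher at both 3 h and 6 h where independent lists would share 0.17 and unchanged arrays 0.12, and 5 were lower at both where these values were 0.15 and 0.13. The excess was not particular to the late arrays, as 6 of 12 genes higher at 0 h were also higher at 3 h, where these values were 0.062 and 0.13, and 2 of 5 lower at 0 h were also lower at 3 h. Part of this excess may come from the untreated array, which cannot be split.

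**Figure D4:**
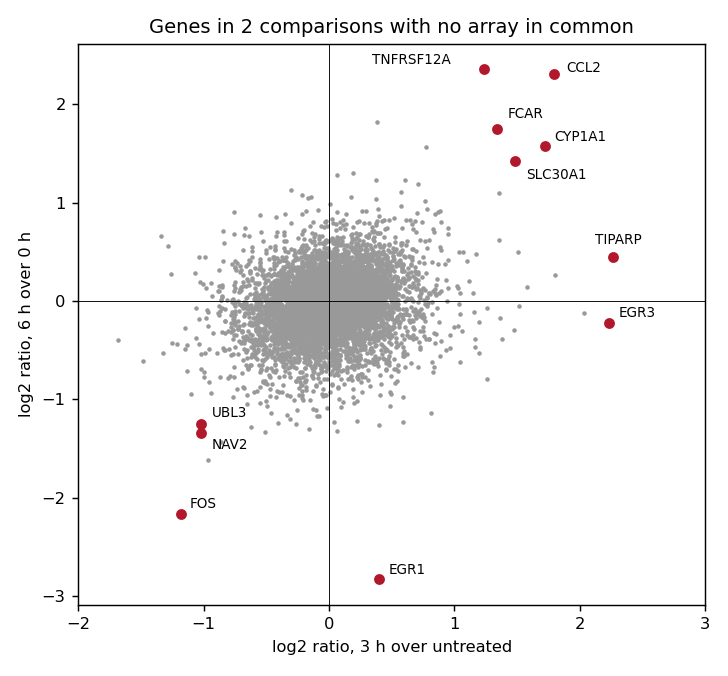
Log2 ratio of 3 h over untreated (horizontal) against 6 h over 0 h (vertical), comparisons with no array in common, for 6612 genes as points. CCL2, TNFRSF12A, FCAR, CYP1A1 and SLC30A1 lie high on both axes, TIPARP and EGR3 only on the horizontal one, and EGR1 is low only on the vertical one.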

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

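Tests chosen only after the result was seen were those on spikes, on the number of probe sets, on drift of the 6 h array with brightness, on ribosomal RNA and on RNA degradation; the others were written before the values they measure. The immediate-early list had opposite medians at different times, 0.17 at 3 h and −0.27 at 6 h over the same untreated array, and this difference was not tested because each time is 1 array. PARG, which degrades poly(ADP-ribose), was at 0.67 at 0 h and at −1.48, a lower bound of its fall, at 3 h, also an untested difference. The probe set 214351_x_at, whose annotation lists SNORD68 and RPL13 and which entered no gene, had log2 ratios over untreated of 1.17, 1.45 and 1.32 at 0, 3 and 6 h. A control probe set of the manufacturer for 28S ribosomal RNA, AFFX-M27830_M_at, left out of all counts, was at 1.11 at 3 h and 2.496 at 6 h, with signals of 234, 295, 505 and 1322 on the 4 arrays in order.

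Ribosomal protein genes had a median log2 ratio of 0.25 at 3 h. Lists drawn from the 20 nonribosomal genes nearest in brightness to each member had a typical median of 0.17. Without the outer 5% they ran from 0.09 to 0.20, and 99.06% of them lay below the ribosomal median. Stretched signal of bright genes could thus account for much of the shift, and whether for all of it is not settled. The highest signal on the 3 h array, 63520, was that of a member, RPS19, so its neighbours were dimmer there. The Cre and BioD hybridisation spikes were at 0.11 (SD 0.11, 8 probe sets), below the ribosomal median by more than their SD, though the highest reached 0.26. All 18 spikes had a median of 0.17 (SD 0.11), within their SD of the ribosomal median. The spikes therefore do not settle whether hybridisation differed enough. Quantile normalization ended the call, at a median of 0.064 inside the random range, since by construction it forces the bright end of all arrays to one distribution. Any real remainder could be a change in these transcripts after paeoniflorin or a difference of the 3 h culture, which 1 array cannot separate.

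The probe sets shared by HSPA1A and HSPA1B were 2-fold higher at 6 h in 3 of 3 cases, which argues against a single faulty probe set. The 2839 probe sets of the same brightness, these 3 included, had a median of −0.028 (robust SD 0.29). Among them 10, again with these 3 included, were as high as the lowest of these 3. That argues against drift of the 6 h array with brightness. A difference of the 6 h culture other than paeoniflorin cannot be told apart from the treatment, since there is 1 array per condition. An effect of paeoniflorin on HSPA1A or HSPA1B transcripts may therefore be kept as a hypothesis, and it remains open which gene the signal comes from.

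Immediate-early genes had a median of −0.27 at 6 h, and of 0.033 without probe sets ending in _x_at or _s_at, among which are several of the lower genes. General loss of 5' ends by RNA degradation is argued against by the 3' to 5' ratios of ACTB and GAPDH, which at 6 h were at most 1.003 times the highest of the other arrays. A different RNA composition of the 6 h sample stays open. The 7 control probe sets for ribosomal RNA that reached the floor had a median log2 ratio of 0.15 (SD 1.08), and 2 of them, both for 28S, were 2-fold higher, the highest at 2.496. The other 28S probe sets went both ways, at −0.40, at −0.60 or lower, and at least at 0.63. Lists matched on brightness had a mean median of −0.031 and, without the outer 5%, a range of −0.18 to 0.11. The list's value lay below that range, but this is the comparison by which it was called apart. It therefore adds no separate evidence on drift with brightness. With the 0 h array as baseline the median was −0.21, below a random range of −0.17 to 0.11, so the shift does not rest on the untreated array alone. Handling or time in culture before the later harvest stays open beside paeoniflorin and could act on genes this short-lived, because the labels do not say when the untreated culture was harvested.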

How the results depend on the processing

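No paired analysis was possible because each condition is 1 array, and for the same reason no array could be left out in turn. The heat shock list with shared probe sets was the 1 alternative chosen after seeing the data. Its medians were −0.02, 0.00 and 0.00, inside the random range of the list without those probe sets. No random lists were drawn for the longer list. Of 78 gene values past 2-fold, 78 stayed so with quantile normalization, with centring, with a floor at the 40th percentile and with no floor. With a floor at the 60th percentile 44 did and 34 were weaker, as a higher floor shrinks the ratios of dim genes. With the median over probe sets 55 stayed and 23 were weaker, and with the 0 h array as baseline 40 of 62 stayed. Some of the 23, such as SQSTM1 and DLEU2, had no other probe set at or above the floor, so probe sets under it weakened them. Without probe sets ending in _x_at or _s_at 48 of 55 stayed, and 2 reversed, ATP2C1 at 0 h (−0.054) and ICAM2 at 3 h (−0.025), through another probe set of the gene.

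The counts of 2-fold genes and probe sets depended on the floor, since dim signals vary more: the robust SD was 0.30 to 0.37 in the 4 dimmest of 20 brightness bins and 0.08 in the brightest. At 0 h, 12 genes higher and 5 lower became 35 and 45 with a floor at the 40th percentile, 3 and 0 at the 60th and 663 and 696 with no floor. At 3 h, 39 and 26 became 117 and 56, 18 and 13, and 1006 and 618 in the same order. At 6 h, 30 and 40 became 59 and 105, 18 and 25, and 704 and 764. For probe sets under these floors, 19 and 11 at 0 h became 71 and 98, 6 and 3, and 1366 and 1534, 67 and 55 at 3 h became 219 and 128, 25 and 21, and 2010 and 1311, and 51 and 89 at 6 h became 104 and 230, 31 and 36, and 1479 and 1660. A rule of 1.5-fold gave 109 and 110 genes at 0 h, 256 and 262 at 3 h and 209 and 380 at 6 h, and 203 and 215, 473 and 517, and 368 and 677 probe sets. A rule of 3-fold gave 0 and 0, 6 and 1, and 5 and 2 genes, and 1 and 0, 8 and 1, and 6 and 4 probe sets. Without probe sets ending in _x_at or _s_at, which leaves fewer to count, the numbers were 7 and 3 genes at 0 h, and 8 and 6, 38 and 26, and 27 and 45 probe sets.

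Genes 2-fold higher on both late arrays numbered 5, and 104 with no floor or 2 without probe sets ending in _x_at or _s_at. Those lower numbered 2, and 57 with no floor and 0 with centring, with a floor at the 60th percentile or without those probe sets; the cause was not tested. All other counts stayed within 1.5 times, and correlations moved by less than 0.1.

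Of the 11 lists that stood apart, 11 did so with centring, and the causes of the losses that follow were not tested. Quantile normalization ended 2 calls, ribosomal proteins at 3 h (0.064) and proteasome at 6 h (0.071). A floor at the 40th percentile ended immediate-early at 3 h (0.13) and granule genes at 6 h (−0.070). A floor at the 60th ended immediate-early at 3 h (0.13) and 6 h (−0.072) and proteasome (0.11). With no floor, immediate-early at 3 h (0.084), granule genes (−0.072) and anti-apoptotic genes at 6 h (0.22) no longer stood apart. The median over probe sets ended metallothioneins (−0.075) and anti-apoptotic genes at 0 h (0.099) and 6 h (0.17). Without probe sets ending in _x_at or _s_at, the unfolded protein response (0.013) and immediate-early (0.033) lists at 6 h changed sign, and calls ended for immediate-early at 3 h (0.077) and, at 6 h, granule (−0.070), proteasome (0.075), anti-apoptotic (0.12) and cholesterol (0.17) genes. The 0 h baseline turned the anti-apoptotic list at 6 h (−0.069) and ended the unfolded protein response (−0.028), proteasome (0.086) and immediate-early 3 h (0.087) calls.

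Lists that stood apart under an alternative alone were NRF2 at 0 h with floors at the 40th (−0.070) and 60th (−0.058) percentile and with no floor (−0.063), heat shock at 3 h with no floor (−0.14), and, with a floor at the 60th percentile, interferon at 3 h (0.18) and p53 targets at 6 h (0.30). With the 0 h baseline these were splicing at 6 h (0.12) and, at 3 h, metallothioneins (0.20), monocyte and macrophage (0.22) and NF-kB (0.35) genes; the cause was not tested.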

Other observations

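Both tests reported here were chosen after the result was seen. One hypothesis concerns the aryl hydrocarbon receptor, a ligand-activated factor whose known targets include CYP1A1 and TIPARP. TIPARP was 4.81-fold and CYP1A1 at least 3.30-fold higher at 3 h, and CYP1A1 was still at least 2.90-fold higher at 6 h. With a floor at the 60th percentile the log2 ratios of CYP1A1 fell under 2-fold, to 0.86 at 3 h and 0.67 at 6 h. If the receptor were active, other known targets might be higher too. Of 4 others measured, 1 was at least 1.5-fold higher at 3 h, NQO1 at 0.77, which is also in the NRF2 list and has another probe set at −0.76. NFE2L2 and SLC7A5 were at −0.12 and 0.07, and CYP1A2 was lower by a bound of −0.12 (its 3 h signal was under the floor), while CYP1B1, ALDH3A1 and EREG lay below the floor. The number of measured targets is too small to decide.

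A second hypothesis, a zinc response through the factor MTF1, would link SLC30A1, 2.80-fold higher at 3 h and 2.75-fold at 6 h, with the metallothionein genes, which MTF1 also controls and which could then be higher as well. The higher of their medians at the late times was 0.091 (6 genes, SD 0.16), at 6 h, and by the brightest probe sets 0 of 6 reached 1.5-fold at any time. A second MT1F probe set, however, was at 1.01 at 3 h and 1.33 at 6 h, which would go with the explanation. With the highest probe set of each gene the median at 6 h was 0.18 (SD 0.53), and 1 of 6 reached 1.5-fold. Over the 0 h array their median at 3 h was 0.20 and stood apart. Part of this may come from the 0 h array, where their median over untreated was −0.11 and stood apart as low. Over untreated their 3 h median was 0.05, inside the random range. A rise shared by all metallothionein genes was not seen, and the explanation stays open.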
